A study of Homo sapiens with 4 samples.

How the data were processed

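The series measured messenger RNA in HepG2 cells, an established human hepatoma line, on Affymetrix HG-U133 Plus 2.0 GeneChips, where each transcript is read by sets of short probes. Per the labels, cells were kept in medium with 25 mM glucose and 10% serum, transfected with small interfering RNA (siRNA) at about 50% confluence and harvested after 4 days. There were 4 arrays. The 2 control arrays carried RNA from cells given an siRNA against GL3, and the 2 knockdown arrays carried RNA from cells given siRNA against LSD1 (gene KDM1A), a different siRNA on each array. Groups and replicate numbers were taken from the sample titles. The labels do not say that arrays of a group came from separate cultures. P-values for single genes therefore measure only the spread between these arrays, which may be technical.

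The deposited values, taken here to be log2, were made by the authors with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes. The software version, and whether control and knockdown arrays were normalized together, are not given in the sources used here. The log base is not stated; 2 is the base RMA gives. The values themselves show 1 further step by the authors: in each of the 54675 probe sets the median of the 4 arrays was 0, with a largest deviation of 5.0e-07. Absolute levels are therefore gone, while differences between arrays of the same probe set remain. Centring also makes control and knockdown arrays correlate negatively over probe sets, so such correlations were not read. The medians of the arrays lay between -0.0152 and 0.0066, and no further normalization was applied. An array gives no counts or depth; the number of arrays limits the precision.

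Because levels were removed, a stand-in for brightness was read from the numeric step of the values. Single-precision numbers have a coarser step above 8 than from 4 to 8 or below 4, and that step survives centring. It placed 22.5% of probe sets at 8 or above, 37.4% from 4 to 8 and 39.4% below 4, with no step found for 0.7%. About 1 row in 8 falls by chance into the next brighter class. The design fixed before the data were examined had called for the probe set with the highest mean per gene, and for a median level in the rule for named genes and in the filter on dim genes. The class took the place of the mean in all of these. For each gene the brightest class was used, then probe sets without a letter suffix before those with _a_at, _s_at or _x_at, then the identifier. Genes counted as dim below 4.

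Probe sets were named through the platform annotation with symbols updated by gene identifier. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and were not used for any gene, and 11777 are unnamed here. The 62 Affymetrix control probe sets were left out of gene tests. This left 19775 genes, of which 19734 were matched by gene identifier to the RefSeq table, and 10523 had over 1 probe set. The 12 probe sets at 0 on all 4 arrays, which give no step, were at first eligible as a gene's probe set. They were ranked last after a first fit had been seen, and that choice decides whether 1 gene or 0 genes pass the threshold, as the closing section states.

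Knockdown and control were compared with limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes moderation, two-sided test, Benjamini-Hochberg adjustment over all genes, threshold 0.05), 2 arrays against 2, with no replicate block. Errors are the standard errors of that fit. The prior had 2.35 degrees of freedom and a standard deviation of 0.134. Each siRNA alone and the difference between the siRNAs were tested in a limma model with 3 groups. Its spread comes from the 2 control arrays alone, so a lone knockdown array is assumed to vary like the controls; the prior had 1.97 degrees of freedom and a standard deviation of 0.066. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.33, so none is reported.

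There were 37 gene lists, fixed before the data were examined, with 933 genes of which 850 were measured. They were tested with limma's camera, which asks whether a list's genes shift more than other genes. It used a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. With that preset, p rests on the spread across genes rather than between arrays, and is too small where list members are more strongly correlated. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. With an estimated correlation, both that correlation and p rest on the spread between the few arrays within groups. That setting therefore has little power, and not passing it does not decide for or against a list. Members were also counted after adjustment over the list alone. For each list the text counts members for which both knockdown arrays lay beyond both control arrays. Chance gives 16.7% in each direction if all arrays spread alike, and more where the knockdown arrays spread more widely, as here. Over all genes the shares were 23.7% higher and 25.4% lower.

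Named genes were chosen by a rule fixed before the data were examined. KDM1A came first. For knockdown against control the rule took the 12 highest and 12 lowest differences among genes past the threshold that had both knockdown arrays beyond both controls and a level class of 4 or above (or, for a step that implies values from 2 to 4, a difference of at least 2); where fewer passed, it took the next genes by moderated t, said not to have passed. For siRNA-2 against siRNA-1 it took the 5 largest differences each way among genes past that test, under the same level rule. For each list it took up to 4 members with the smallest p. PPARGC1A, HIF1A, SLC2A1 and MYC were named in any case. Other names in the text were chosen after their values were seen and are marked so.

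On simulated data with spreads drawn from the fitted prior, 200 of the 19775 genes were changed. For siRNA-2 that prior came from the controls alone. The siRNA-2 array spread more widely over probe sets (SD 0.384) than the controls (0.163 and 0.154). If part of that is noise, false calls on it are more frequent than simulated. The test of 2 against 2 arrays recovered 81.5% of 4-fold changes with 6 false calls, and 0% of 2-fold changes. The test of siRNA-2 against control recovered 92.0% of 4-fold changes with 16 false calls, and 0% of 2-fold changes. Recovery under this adjustment depends on how many genes change, and only 200 were changed here. On the data the siRNA-2 test also called differences under 2-fold, such as TKT at 0.38. The simulated 0% therefore does not describe that test on the data. The list test found a shift of 0.5 in 25 genes in 50 of 50 draws. It made 0 false calls among the other lists counted, which left out the NRF2 targets and glutathione list. Genes were drawn independently, so the simulation cannot show false calls that correlated genes would cause.

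Alternatives covered a trend of the variance on the level class, array weights, robust moderation, centring each array, leaving out dim genes, the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, testing each probe set, a replicate block, leaving out each array, and other thresholds and list tests. Quantile normalization of the deposited values was planned and not run, since values centred per probe set have no levels to equalise. The shared replicate numbers do not pair the arrays by any statement in the labels. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.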

Results

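Expression was measured on 4 arrays of HepG2 cells, a human hepatoma line, to ask what depletion of the histone demethylase LSD1 does to gene expression in hepatic cancer cells, with metabolism named in the study's title. Control cells received an siRNA against GL3 (2 arrays), and knockdown cells received siRNA-1 or siRNA-2 against LSD1 (1 array each). Values are RMA values, taken to be log2, that the authors centred per probe set, so differences between arrays are given and levels are not. Across probe sets the SD of the centred values was 0.163 and 0.154 on the control arrays, 0.196 with siRNA-1 and 0.384 with siRNA-2. No gene differed by more than 2-fold between the controls (0 of 19775), whereas 752 differed that much between the knockdown arrays. P-values for single genes measure only the spread between these arrays, which the labels do not describe as separate cultures. Those of the list test with a preset correlation rest on the spread across genes, taken as nearly independent. Calls for a single siRNA, or between the siRNAs, assume that 1 array varies like the 2 controls, and describe these arrays.

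KDM1A, the gene that encodes LSD1, was lower on both knockdown arrays. Its 1 probe set read 1.23 and 1.17 on the control arrays, -1.55 with siRNA-1 and -1.17 with siRNA-2. The difference was -2.56 ± 0.16 (SE, n = 2 arrays per group), a 5.91-fold lower level. It did not pass the limma test over all genes (adjusted p = 0.0852). With the spread of the controls alone, KDM1A read -2.37 with siRNA-2 and -2.75 with siRNA-1, with a standard error of 0.071 for each. It passed with siRNA-2 and not with siRNA-1. For each siRNA its adjusted p was the smallest that any gene reached, so this does not rank the siRNAs. Over 14 alternative settings the adjusted p ran from 0.0163 to 0.999, and the difference stayed between -2.75 and -2.37.

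CD36, a membrane receptor that takes up long-chain fatty acids, rose 11.8-fold on knockdown (3.56 ± 0.11 on the log2 scale, SE, n = 2 arrays per group). It was the only gene past the threshold in the comparison of knockdown with control (1 higher, 0 lower, limma adjusted p = 0.0477). The values were 3.54 with siRNA-1 and 3.58 with siRNA-2, and further CD36 probe sets read 2.77 and 3.48 with siRNA-1, while a pair of dim ones stayed at -0.05 and 0.30. The call ended in 9 of 15 alternative settings, among them robust moderation (adjusted p = 0.0502) and leaving out control 1 (0.999), control 2 (0.978) or the siRNA-2 array (0.0863), with a range from 0.0163 to 0.999 over all of them. At an unadjusted p under 0.05 there were 2913 genes, against 989 by chance, and 56 genes had an adjusted p under 0.1, 41 higher and 15 lower.

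The next genes in order of the test did not pass, and each lay beyond the controls on both knockdown arrays. Those with higher values included DIO1 (2.62 ± 0.12), which encodes the liver deiodinase that activates thyroid hormone, KLB (1.62 ± 0.10), the co-receptor of FGF21, and SLC30A10 (2.44 ± 0.13), a manganese exporter. The complement gene C8B (1.68 ± 0.11), the muscle troponin gene TNNC2 (2.71 ± 0.12) and SMTNL2 (2.58 ± 0.15) had values in the same range. PLA2G1B (1.85), OLFML3 (1.95), ADGRG1 (1.84), KLHL13 (1.57) and ENPP2 (1.54), the gene of autotaxin, completed this group, with adjusted p from 0.0545 to 0.0866. The second probe set of ADGRG1 read 0.21 with siRNA-1 and -0.11 with siRNA-2.

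Genes with lower values included the glycerol and water channel AQP3 (-2.71 ± 0.12), the immediate-early transcription factor EGR1 (-2.49 ± 0.10) and IGFBP1 (-1.77 ± 0.15), a secreted binding protein for insulin-like growth factors. ENO2, an enolase of glycolysis, had a difference of -1.08 ± 0.10. RAMP1 (-1.86), PAEP (-1.62), LCN15 (-1.47), MPP1 (-1.42), MOSPD1 (-1.37), AKAP12 (-1.23) and ASB4 (-1.22) followed. Adjusted p for these genes ran from 0.0545 to 0.0968, so none passed. Without _x_at and _s_at probe sets ASB4 turned to 0.26, through 1 probe set, while another outside those classes read -1.16 with siRNA-1 and -1.32 with siRNA-2. Among all other probe sets of the 24 genes named, 17 of 22 went the same way with both siRNAs, and 13 of 15 when dim ones were left out.

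**Figure D1:**
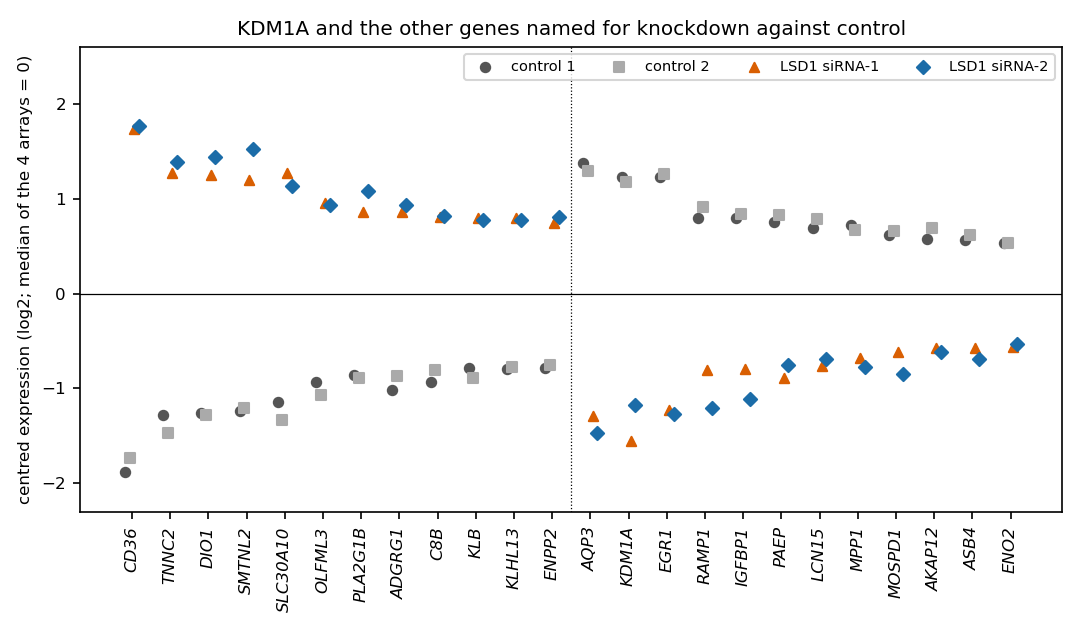
Centred log2 expression of the 24 genes named for knockdown against control (horizontal axis, higher genes left and lower genes right of the dotted line) on each of the 4 arrays; points are single arrays without error bars. CD36 lay at -1.88 and -1.73 on the control arrays and at 1.73 and 1.77 on the knockdown arrays, and KDM1A at 1.23 and 1.17 against -1.55 and -1.17.

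A count chosen after the data were seen gives the genes that differed at least 2-fold from the control mean with each siRNA in the same direction. There were 133 higher and 49 lower genes, and 0 in opposite directions. Independent lists of the observed sizes would share 7.4 higher and 1.9 lower genes. Simulated arrays with no effect and shared controls gave a mean of 0.03 genes. All of these were given the narrow spread of the controls, so a count near 0 was fixed in advance. A batch difference between control and knockdown arrays would also be shared by both siRNAs. Picked from this group after their values were seen, the kininogen gene KNG1 (2.52 with siRNA-1, 3.07 with siRNA-2), PON1 (2.30 and 3.83), the fatty acid binding protein gene FABP1 (1.05 and 3.51) and MTTP (1.59 and 1.62), needed for lipoprotein assembly, were higher. EGR3, read by a dim probe set (-2.72 and -1.42), DUSP5 (-1.65 and -2.37), ANXA1 (-1.33 and -3.04) and IL11 (-1.26 and -2.84) were lower. All other probe sets of the 182 genes went the same way with both siRNAs in 117 of 167 cases, and in 69 of 82 when dim ones were left out.

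Genes that mark hepatocytes by their secreted proteins and transcription factors shifted higher as a list. Of 24 measured members, 21 were higher and 1 lower on both knockdown arrays than on both controls, with a median difference of 0.41 (0.24 with siRNA-1, 0.52 with siRNA-2). The list passed camera (adjusted p = 2.59e-05) but not with an estimated correlation (adjusted p = 0.718). No member passed over all genes, and 6 were higher when adjusted over the list alone. The apolipoprotein genes APOH (0.95 ± 0.16) and APOE (0.84 ± 0.19) and the fibrinogen genes FGA (0.73 ± 0.17) and FGG (0.48 ± 0.10) had the smallest p. With siRNA-2 alone 13 members rose and 1 fell. FGA read about 0 when _x_at and _s_at probe sets were left out, and 19 of 30 other probe sets of the 21 higher members were higher with both siRNAs.

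Acute phase and complement genes, which encode liver-made plasma proteins of inflammation and innate defence, also shifted higher. The median difference over 17 members was 0.45 (0.20 with siRNA-1, 0.47 with siRNA-2), with 11 higher and 0 lower on both knockdown arrays, and camera gave an adjusted p of 4.47e-04 (adjusted p = 0.718 with an estimated correlation). HPX, encoding the haem carrier hemopexin, read 1.83 ± 0.20, SERPINA3 1.64 ± 0.18, C8A 1.40 ± 0.12 and C3 1.16 ± 0.19. When adjusted over the list alone 4 members were higher, against 0 over all genes, and with siRNA-2 9 rose and 1 fell.

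Lists of lipid-synthesis genes were higher. The 19 cholesterol biosynthesis genes had a median difference of 0.74 (0.22 with siRNA-1, 1.11 with siRNA-2; adjusted p = 0.00116, and adjusted p = 0.740 with an estimated correlation). With siRNA-2, 16 of them rose and 0 fell, and 11 were higher with siRNA-2 than with siRNA-1 in the test of that difference. HMGCS1 (0.94 ± 0.24), SQLE (0.83 ± 0.26), SC5D (0.77 ± 0.31) and HSD17B7 (0.75 ± 0.26), enzymes of sterol synthesis, were the members with the smallest p. The fatty acid and triglyceride synthesis list had a median of 0.43 over 23 members, with 0.19 for siRNA-1 and 0.56 for siRNA-2, a difference not tested for the list (adjusted p = 5.17e-04, and adjusted p = 0.718 with an estimated correlation). Its acetyl-CoA carboxylase gene ACACB read 1.23 ± 0.25, the lipase gene PNPLA3 1.28 ± 0.42, and MLXIPL, the carbohydrate-response transcription factor, 1.13 ± 0.28. PLIN2, a lipid droplet coat protein, went the other way at -0.69 ± 0.17. Neither list had a member past the test over all genes or when adjusted over the list alone; with siRNA-2, 12 of the 23 rose and 1 fell. Without _x_at and _s_at probe sets the adjusted p of the fatty acid and triglyceride list was 0.0728, the highest of 11 settings whose lowest was 0.00013.

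Fatty acid oxidation genes had a small upward shift, with a median of 0.14 over 25 members (0.17 with siRNA-1, 0.33 with siRNA-2), 13 higher and 4 lower on both knockdown arrays. Camera gave an adjusted p of 0.00845 (adjusted p = 0.718 with an estimated correlation). EHHADH, an enzyme of peroxisomal oxidation, read 1.47 ± 0.28, ECI2 0.65 ± 0.10, DECR1 0.55 ± 0.11 and ACADSB 0.43 ± 0.10, and 3 members were higher when adjusted over the list alone (0 over all genes). The call ended without the siRNA-1 array (adjusted p = 0.0694) and without _x_at and _s_at probe sets (0.134), and over 11 settings the adjusted p ran from 0.00528 to 0.134.

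Glycolysis genes shifted lower. Of 22 members 14 were lower and 3 higher on both knockdown arrays, with a median of -0.26 (-0.17 with siRNA-1, -0.29 with siRNA-2) and a mean of -0.12 (adjusted p = 0.0232, and adjusted p = 0.718 with an estimated correlation). The glucose transporter gene SLC2A1 read -0.67 ± 0.15, HK1 -0.79 ± 0.19 and ENO2 -1.08 ± 0.10, while PFKM, the muscle form of phosphofructokinase, read 1.46 ± 0.11. When adjusted over the list alone 1 member was lower (ENO2) and 1 higher (PFKM), and 0 over all genes; with siRNA-2 9 members fell and 4 rose. Of 17 other probe sets of the 14 lower members, 8 were lower with both siRNAs. The adjusted p was 0.0883 without the siRNA-1 array and 0.0704 with the mean of each gene's probe sets, in a range from 0.0124 to 0.0883 over 11 settings.

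Oxidative phosphorylation and the tricarboxylic acid cycle did not shift, with medians of 0.01 over 69 genes (adjusted p = 0.908) and 0.01 over 21 genes (adjusted p = 0.908). NDUFS7 of respiratory complex I was the largest exception among the genes named for the first list, at -0.73 ± 0.12. COX7C (0.39), UQCR10 (0.35) and CYC1 (-0.30) lay on either side of 0, as did IDH3A (-0.48) and SUCLG2 (0.46) of the cycle. PPARGC1A, the coactivator of mitochondrial biogenesis, read 0.52 ± 0.21 (0.79 with siRNA-1, 0.25 with siRNA-2; adjusted p = 0.363). Regulators of mitochondrial biogenesis, PPARGC1A among them, had a median of -0.16 (adjusted p = 0.238).

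The mitochondrial ribosome shifted lower by a median of -0.18 over 51 genes (-0.09 with siRNA-1, -0.25 with siRNA-2), 29 lower and 4 higher on both knockdown arrays (adjusted p = 5.97e-04, and adjusted p = 0.740 with an estimated correlation). MRPS12 (-0.60 ± 0.17), MRPS34 (-0.55 ± 0.15), MRPS14 (-0.38 ± 0.10) and MRPS17 (-0.36 ± 0.10) were the members with the smallest p. The list of MYC targets and ribosome biogenesis factors had a median of -0.25 over 21 genes (adjusted p = 0.00296, and adjusted p = 0.740 with an estimated correlation). That median was -0.05 with siRNA-1 and -0.48 with siRNA-2, and without the siRNA-2 array the adjusted p was 0.0803, against 0.000285 at the other end of 11 settings. MYC itself read -0.33 ± 0.23, with -0.02 for siRNA-1 and -0.64 for siRNA-2; ODC1 (-0.49) and PES1 (-0.48) were lower with each siRNA. Neither list had a member past the test over all genes or over the list alone, and with siRNA-2 16 mitochondrial ribosome genes fell and 3 rose, and 11 of the MYC list fell and 0 rose. The cytosolic ribosome had a median of 0.00 (adjusted p = 0.908).

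Targets of NRF2, the oxidative stress transcription factor, and glutathione genes had a median of 0.17 over 20 members, 10 higher and 3 lower on both knockdown arrays (adjusted p = 0.0153, and adjusted p = 0.718 with an estimated correlation). The haem oxygenase gene HMOX1 read 0.94 ± 0.11, GPX2 0.73 ± 0.14, PGD 0.60 ± 0.11 and AKR1C2 0.43 ± 0.11; 3 members were higher when adjusted over the list alone and 0 over all genes. The median was larger with siRNA-1 (0.39) than with siRNA-2 (0.11), a difference that was not tested for the list, and without the siRNA-1 array the adjusted p was 0.461, in a range that began at 0.00679 over 11 settings. With siRNA-2, 3 members rose and 3 fell.

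On the arrays where these lists shifted, control probe sets differed too. Hybridization spike-ins, transcripts added in fixed amounts before hybridization, read -0.69 and -0.61 on the control arrays and 0.61 and 0.65 on the knockdown arrays, a difference of 1.28 (2.44-fold) with a range of 0.80 to 1.53 over 18 probe sets. The 5' probe set of ACTB relative to its 3' probe set was 0.61 log2 units lower on the knockdown arrays (-0.61), and that of GAPDH was lower as well (-0.18). Poly-A spike-ins, added before labelling, read -0.37 and -0.04 on the controls and 0.14 and 0.05 on the knockdown arrays. Every list shift above runs along the same split of arrays.

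**Figure D2:**
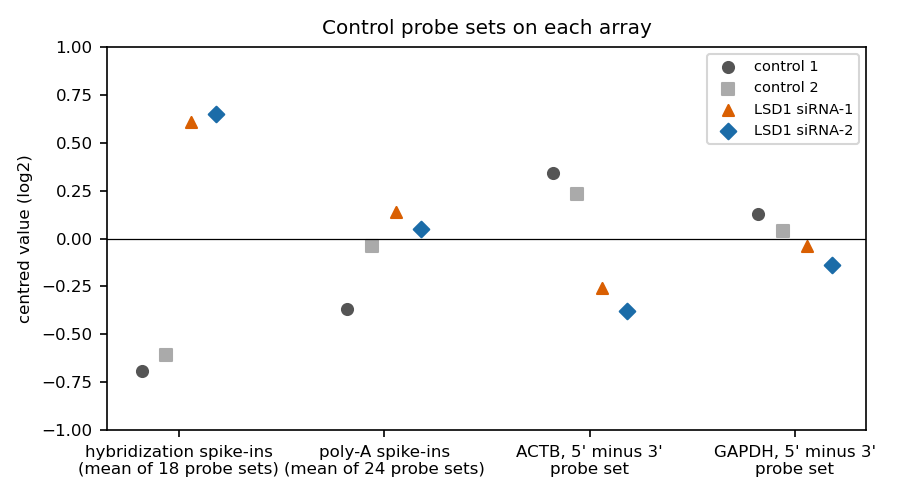
Centred log2 values of control probe sets on each of the 4 arrays: means over hybridization and poly-A spike-ins, and the 5' minus 3' difference for ACTB and GAPDH; points are single arrays. The hybridization spike-ins lay at -0.69 and -0.61 on the control arrays and at 0.61 and 0.65 on the knockdown arrays.

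In total 9 of 37 lists passed camera, 6 higher and 3 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.718), and fry also passed 0. The estimated correlation has little power with so few arrays, so its adjusted p does not weigh any single list. Among lists that did not pass, serine and one-carbon genes had a median of 0.19 (adjusted p = 0.0627), with BHMT at 2.07 ± 0.15, MAT1A at 0.94 ± 0.20, AMT at 0.67 ± 0.15 and PSAT1 at -0.66 ± 0.11; this list passed without dim genes (0.0297), without _x_at and _s_at probe sets (0.0205) and without the siRNA-2 array (0.0432). Targets of p53 had a median of 0.20 (adjusted p = 0.0934), with SPATA18 at 1.22 and GDF15 at -1.03; this list passed without the siRNA-1 array (0.0225). Interferon response genes had a median of 0.02 (adjusted p = 0.102), with IFIT1 at 1.34 ± 0.10 and IFI27 at 1.79 ± 0.41; the list passed without dim genes (0.0297), with the mean of probe sets (0.0235) and without the siRNA-2 array (0.0173). Bile acid and drug metabolism genes had a median of 0.09 (adjusted p = 0.30), with SULT2A1 at 2.23 ± 0.51. Amino acid and urea metabolism genes had a median of 0.06 (adjusted p = 0.316), with CPS1 at 1.31 ± 0.39 and HPD at 0.79 ± 0.15, and the list passed with the mean of probe sets (0.0348) and without the siRNA-2 array (0.0432). Gluconeogenesis genes had a median of -0.03, a mean of 0.04 and a downward test (adjusted p = 0.908), and the glucose transporter gene SLC2A2 read 0.85 ± 0.25.

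Some further lists on growth and stress did not pass with all 4 arrays. Median differences were -0.08 for DNA replication (adjusted p = 0.889), 0.02 for mitosis (0.899; -0.14 with siRNA-1, 0.21 with siRNA-2), -0.02 for ATF4 and the unfolded protein response (0.908), -0.10 for lysosome and autophagy (0.185) and 0.02 for Wnt targets (0.407). The lysosome and autophagy list passed, lower, without the siRNA-2 array (0.0221), and the cell cycle inhibitors passed, lower, without control 1 (0.0487). These inhibitors had a median of 0.00, a mean of -0.27 and a camera adjusted p of 0.185. When adjusted over the list alone 3 of 13 were lower. KLF4 read -1.17 ± 0.11, and CDKN2B, read by a dim probe set, -2.01 ± 0.22. Over the alternatives CDKN2B ran from -2.23 to -1.2. Hypoxia and HIF1A targets had a median of 0.01, a mean of -0.07 and a downward test (adjusted p = 0.575). HIF1A read 0.09 ± 0.14, with 0.24 for siRNA-1 and -0.06 for siRNA-2. The pentose phosphate pathway had a median of -0.03, a mean of 0.04 and an upward test (adjusted p = 0.669), with TKT at 0.43.

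The LSD1 complex list, KDM1A included, had a median of 0.00, a mean of -0.14 and an adjusted p of 0.669. Without KDM1A, a setting added after the data were seen, the 16 partners had a median and mean of 0.01 and a downward test (adjusted p = 0.91). GSE1 read -0.71 ± 0.12 and RCOR2 -0.32 ± 0.10, while ZNF217 was higher with each siRNA (0.59 and 1.41) and RCOR3 read 0.38 ± 0.13. Neuronal genes held down by REST and CoREST, a complex that LSD1 belongs to, had a median of 0.00 and a mean of -0.06 over 29 genes (adjusted p = 0.808), with CHGB at 0.86 ± 0.20 and VGF at -2.25 ± 0.42. Chromatin demethylases and methyltransferases had a median of -0.01, a mean of 0.03 and an upward test (adjusted p = 0.908); DNMT3B read 1.42 ± 0.16 and JMJD6 -1.02 ± 0.19. Fetal liver and progenitor genes had a median of -0.10 (adjusted p = 0.908), with EPCAM at 1.11 ± 0.15 and IGF2BP1 at -0.90 ± 0.14. Epithelial and mesenchymal genes had a median of -0.06, a mean of 0.18 and an upward test (adjusted p = 0.908), with the cadherin gene CDH1 at 2.18 ± 0.48 and CLDN1 at 1.79 ± 0.42.

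Markers of other liver cell types did not pass with all 4 arrays; without the siRNA-2 array the leukocyte markers passed, higher (adjusted p = 0.0185). The medians were 0.05 for leukocytes (adjusted p = 0.30), -0.02 for endothelium (0.426), 0.14 for cholangiocytes (0.554), and -0.04 with a mean of 0.16 and an upward test for fibroblasts and stellate cells (0.908). CD74 (1.69 ± 0.14), COL1A1 (1.88 ± 0.54), ACTA2 (0.66 with siRNA-1, 1.75 with siRNA-2) and ESAM (-1.16 ± 0.15) were single members with large values.

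**Figure D3:**
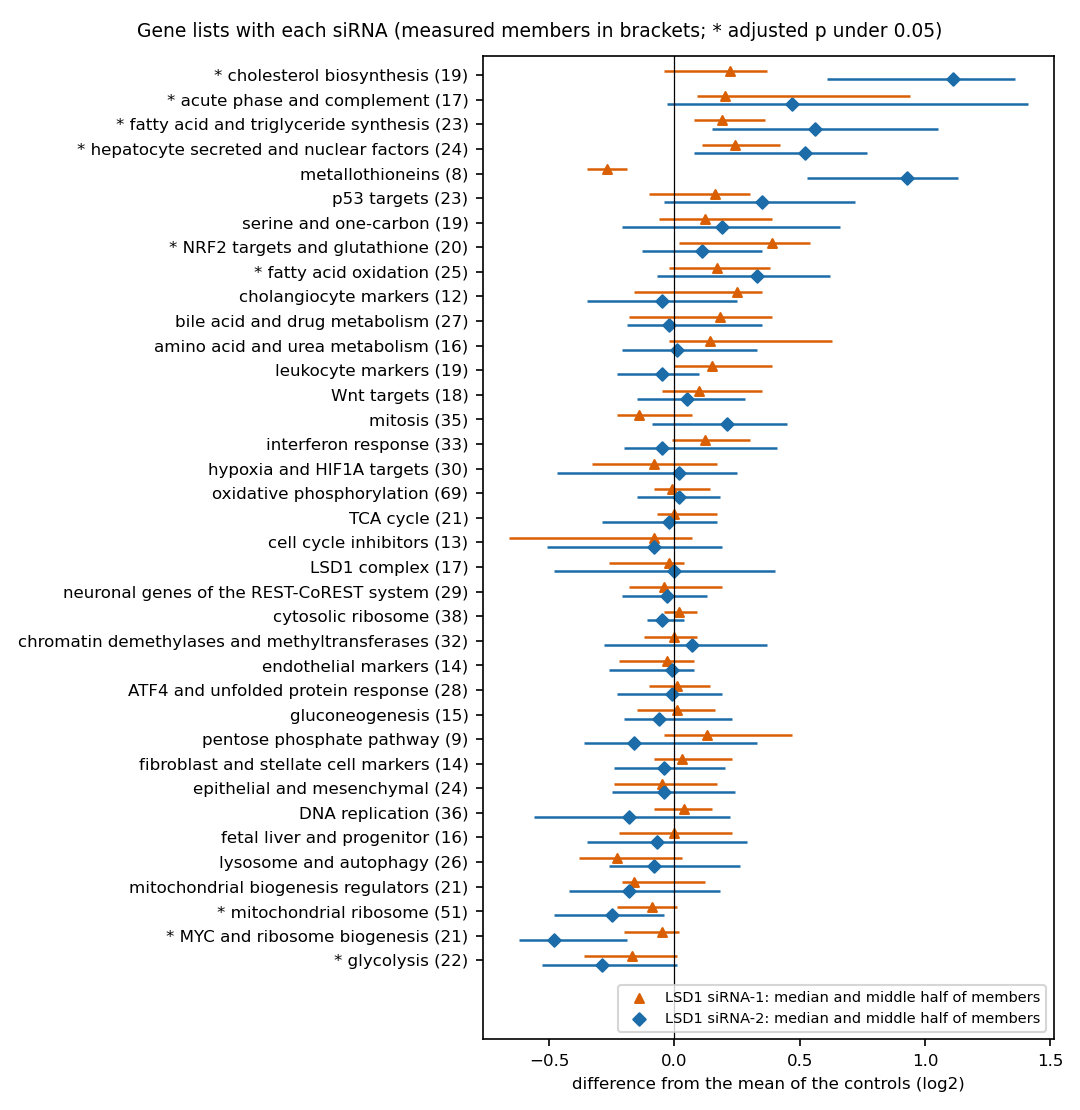
Median difference from the mean of the controls (log2, horizontal axis) for the members of each of the 37 gene lists with siRNA-1 and siRNA-2; lines span the lower to the upper quartile of the members, and asterisks mark the 9 lists past camera in the comparison of knockdown with control. Cholesterol biosynthesis lay at 0.22 with siRNA-1 and 1.11 with siRNA-2, and metallothioneins at -0.27 and 0.93.

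With siRNA-2 alone, the metallothionein gene MT1M rose by 5.31 ± 0.08 (SE, n = 1 array against 2 controls), HSD17B6 by 4.30 ± 0.13 and the sterol enzyme gene HMGCS1 by 1.27, while CARNMT1, a carnosine methyltransferase gene, fell by 2.46 ± 0.07. With siRNA-1 the largest of the values named here were 3.54 for CD36 and 2.90 for SPP1, and neither passed. Taking the lone array to vary like the controls, 2675 genes rose and 2044 fell with siRNA-2 relative to the controls, and with siRNA-1 the same limma model with 3 groups called 0 genes (smallest adjusted p = 0.0863). At an unadjusted p under 0.05 siRNA-1 had 5340 genes and siRNA-2 8143, against 989 by chance, and 753 genes had an adjusted p under 0.1 with siRNA-1. The siRNA-1 count rose to 1105 with a variance trend and to 195 when dim genes were left out. Differences of at least 2-fold numbered 188 higher and 87 lower with siRNA-1 against 783 and 430 with siRNA-2.

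The arrays of the siRNAs differed from each other in 1358 genes, 793 higher and 565 lower with siRNA-2 than with siRNA-1. MT1M was 5.91 higher with siRNA-2, with 5.31 against the controls compared with -0.60 for siRNA-1. HSD17B6, a steroid-metabolising enzyme (3.90), LMLN (2.67), the protease gene PRSS8 (2.61) and the dim COSMOC (2.48) were also higher. The secreted phosphoprotein gene SPP1 was lower by -3.67, reading 2.90 with siRNA-1 and -0.77 with siRNA-2. EREG, a ligand of the epidermal growth factor receptor (-3.11), CARNMT1 (-2.88), CLDN12 (-2.86) and LRRC8B (-2.81) were lower too. Each of these 10 had an adjusted p of 0.0436 in the limma fit, with 1 array on each side. Of 8 metallothionein list members, MT1E, MT1F, MT1G, MT1H, MT1X and MT2A were read by _x_at probe sets, whose probes may bind related transcripts. Their values may therefore not be separate readings. The metallothionein list had medians of -0.27 with siRNA-1 and 0.93 with siRNA-2, and a camera adjusted p of 0.669 for knockdown against control. It passed in opposite directions without 1 knockdown array: lower without the siRNA-2 array (0.0107) and higher without the siRNA-1 array (0.0021). Without _x_at and _s_at probe sets the count between siRNAs was 188.

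Across genes the differences from control with siRNA-1 and siRNA-2 correlated with Pearson r = 0.53 (Spearman rho = 0.45), where genes are not independent replicates. Simulated arrays with no effect and shared controls gave r = 0.33, and the covariance was 0.0866 against a simulated 0.0036. The simulated knockdown arrays had the spread of the controls, so these values are no baseline for arrays that spread more widely. With a separate control for each siRNA, so that no array was shared, r was 0.48 and 0.46. A batch difference between control and knockdown arrays would raise these values too. Relative to both controls both knockdown arrays were higher in 23.7% of genes and lower in 25.4%. Chance gives 16.7% each only for arrays that spread alike. Over genes the SD of the difference was 0.158 between the controls and 0.437 between the knockdown arrays. The 16.7% is therefore no baseline here, and these shares do not show an effect.

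**Figure D4:**
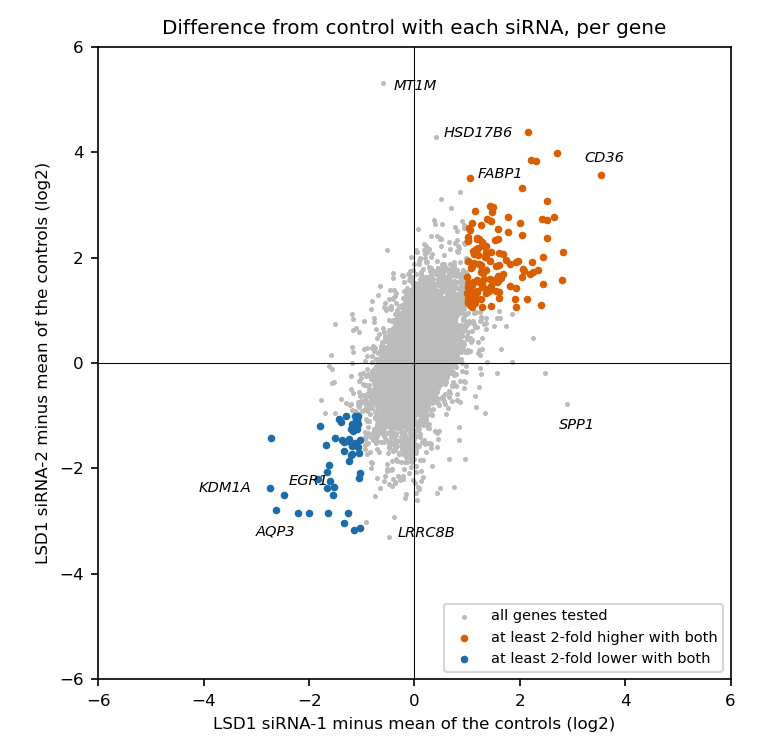
Difference from the mean of the controls (log2) for each of 19775 genes with siRNA-1 (horizontal) and siRNA-2 (vertical); coloured points are the 133 genes at least 2-fold higher and the 49 at least 2-fold lower with both. CD36 lay at 3.54 and 3.58, KDM1A at -2.75 and -2.37, MT1M at -0.60 and 5.31, and SPP1 at 2.90 and -0.77.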

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

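The tests of explanations below were chosen after the results they weigh had been seen; the comparison between siRNAs, the gene lists and the runs without 1 array were not.

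The arrays of the siRNAs differed in 1358 genes by a test of the difference itself, with 1 array a side and the spread of the controls alone, led upwards with siRNA-2 by MT1M (5.91), HSD17B6 (3.90), LMLN (2.67), PRSS8 (2.61) and COSMOC (2.48) and downwards by SPP1 (-3.67), EREG (-3.11), CARNMT1 (-2.88), CLDN12 (-2.86) and LRRC8B (-2.81). Noise of the siRNA-2 array stays open, since all other probe sets of the called genes went the same way in 77.9% of 1742 cases (83.4% of 1212 without dim ones) and could not show noise that a whole array shares. Deeper loss of the target messenger RNA is argued against by the 1 probe set of KDM1A, which read 0.38 higher with siRNA-2 than with siRNA-1. That rests on 1 array for each siRNA. LSD1 protein was not measured, so deeper loss of the protein stays open. A hybridization difference between the knockdown arrays is argued against by the spike-ins, which differed by 0.04. Transcripts other than KDM1A that siRNA-2 may act on stay open: 51.3% of the genes called between the siRNAs lay on the same side of the controls with both, the siRNA sequences were not used here, and with 1 array for each siRNA a difference between cultures cannot be told apart from them either.

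Hybridization spike-ins, which no gene comparison uses, read 1.28 higher on the knockdown arrays. After normalization the arrays lay in line for the cytosolic ribosome genes, whose median difference was 0.00. Quantile normalization itself brings arrays together, so this median cannot weigh a difference in RNA amount that was removed by it. Control and knockdown arrays hybridised as separate batches could account for the spike-ins, which differed by 1.28 between the groups and by 0.08 between the controls (-0.08). Each group would then lie in its own batch, so batch and knockdown cannot be told apart for any comparison with the controls.

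The hepatocyte list was higher and the glycolysis list lower with both siRNAs, calls that neither list kept with an estimated correlation (adjusted p = 0.718 for each) and that glycolysis lost without the siRNA-1 array (0.0883). Fewer cycling cells are argued against for siRNA-2 only by the median of the mitosis genes, 0.21 on 1 array. Members with the smallest p went both ways. Over the alternatives AURKA ran from -0.61 to -0.37 and MAD2L1 from -0.55 to -0.22, against 0.16 to 0.44 for CDK1 and 0.08 to 0.42 for TOP2A. The median of -0.14 with siRNA-1 leaves fewer cycling cells open there. Probe sets that misreport their gene stay open: of all other probe sets of the members beyond both controls 57.4% went the same way (19 of 30 for hepatocyte genes, 8 of 17 for glycolysis). Lower integrity of the knockdown RNA may contribute and stays open, since the 5' probe set of ACTB read -0.61 relative to the 3' probe set and probe positions in other transcripts were not used here. An effect of LSD1 loss, the biological explanation the design names, stays open beside these.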

How the results depend on the processing

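The settings that allow probe sets at 0 on all arrays or average the brightest probe sets, the LSD1 complex list without KDM1A (adjusted p = 0.91 against 0.669), and the count of genes at least 2-fold changed with both siRNAs, were chosen after the data were seen. Against the 1 gene of the comparison of knockdown with control, array weights gave 7 genes and an adjusted p under 0.1 gave 56; robust moderation, leaving out dim genes, the mean of all probe sets, each probe set by itself, and allowing probe sets at 0 on all arrays gave 0 each, with a smallest adjusted p from 0.0502 to 0.0577. Leaving out 1 array gave 0 to 4719 genes; the 4719 came without the siRNA-1 array, when the spread is that of the controls alone. The numbers shared by control and knockdown arrays did not pair them (r = 0.03 between their deviations), and a replicate block on these 2 pairs gave 0 genes and 9 lists, as many lists as without it. KDM1A passed with array weights (-2.56, adjusted p = 0.0385), and leaving out 1 array moved it from -2.75 to -2.37; it has no value without _s_at probe sets.

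For siRNA-1 the count went from 0 to 1105 with a variance trend and 195 without dim genes; between the siRNAs it went from 1358 to 3495, to 3248, and to 188 without _x_at and _s_at probe sets. The siRNA-2 count stayed between 3153 and 5882. Without a control array the model with 3 groups has no residual degrees of freedom and gave no count. Genes changed with both siRNAs numbered 176 to 192 without 1 control, against 182, and 653 at 1.5-fold. Correlation between siRNAs stayed between 0.52 and 0.55. Of 37 lists, 9 passed, against 0 with an estimated correlation, 0 by fry (smallest adjusted p = 0.0518) and 8 to 14 without 1 array. The 14, without the siRNA-2 array, lost the MYC and ribosome biogenesis list and added 6 lists. Metallothioneins and lysosome were lower, and interferon response, leukocyte markers, serine and one-carbon, and amino acid and urea were higher. The 8, without the siRNA-1 array, lost glycolysis (0.0883), fatty acid oxidation (0.0694) and NRF2 (0.461) and added p53 targets (0.0225) and metallothioneins (0.0021), both higher. Without control 1 the cell cycle inhibitors passed, lower (0.0487). Interferon response also passed without dim genes (0.0297) and with the mean of probe sets (0.0235), serine and one-carbon without dim genes (0.0297) and without _x_at and _s_at probe sets (0.0205), and amino acid and urea with the mean of probe sets (0.0348).

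Of 2490 results for named genes under alternatives, 2330 kept their direction and side of the threshold, 135 newly passed (130 of them without the siRNA-1 array, where siRNA-2 alone meets the spread of the controls, and 5 with array weights), 11 no longer passed and 14 changed sign. For knockdown against control only CD36 had passed, so the other genes of that comparison had no call to lose. Their staying on the same side of the threshold says little about stability. CD36 itself passed in 6 of 15 alternative settings. Without _x_at and _s_at probe sets ASB4 read 0.26, IDH3A 0.27, CD163 -0.02, DUT -0.02, FGA 0.00 and TKT 0.00. With the mean of all probe sets ITGAM read 0.02, PECAM1 0.17 and SLC30A1 0.01, and with the mean of the brightest PECAM1 0.20 and SLC30A1 0.00. Leaving out 1 knockdown array moved HIF1A from -0.06 to 0.24, MT1M from -0.60 to 5.31 and MT1X from -0.15 to 1.01, as each is then the value of 1 siRNA. For all other settings the cause was not tested. Quantile normalization was not run, and signal over background was lost with the centring.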

Other observations

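The 4 lists below were written after genes that prompted them had been seen and leave out those genes; no single value of the remaining members had been seen then. Tests of earlier lists had been, and these hold 15 of the PPARA targets and 1 of the MAPK and ERK genes; the PPARA test and all results without those genes were therefore chosen after results were seen.

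Genes induced through MAPK and ERK signalling were lower with both siRNAs. Beyond EGR1, EGR3 and DUSP5, which prompted the list, 19 of 23 members were lower and 1 higher on both knockdown arrays, with a median of -0.59 (-0.45 with siRNA-1, -0.67 with siRNA-2). Camera gave p = 7.55e-10 (limma adjusted p = 3.02e-09 over the 4 lists), and adjusted p = 0.0838 with an estimated correlation, so the call was lost there. The feedback inhibitor gene SPRY4 read -1.03, the immediate-early gene FOS -0.82, FOSL1 -1.20 and IER3 -1.33. EREG was split, with 0.76 for siRNA-1 and -2.35 for siRNA-2, and CXCL8 read 0.38. The median of -0.59 would go with lower MAPK/ERK-induced transcription in the knockdown cells, as a hypothesis that rests on the preset correlation. This hypothesis shares the open batch question of the other comparisons with the controls. The lower 5' readings of ACTB (-0.61) and GAPDH (-0.18) hold on these arrays as well.

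Further hepatocyte plasma protein genes of coagulation, complement and lipid transport were higher. Prompted by C8A, C8B, SERPINC1 and KNG1, the list of 31 other members had a median of 0.35, 19 higher and 2 lower on both knockdown arrays (limma adjusted p = 1.07e-04, and adjusted p = 0.114 with an estimated correlation). SERPINF2 read 1.61, C1RL 1.25 and the coagulation factor gene F5 0.91, while F12 read -0.49. The median of 0.35 extends the hepatocyte shift to genes outside that list and gives no cause for it. The estimated correlation has little power here and does not settle this shift, which rests on the preset correlation. The lower 5' readings of ACTB (-0.61) and GAPDH (-0.18) and the open batch question hold on these arrays too.

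Targets of the nuclear receptor PPARA, prompted by CD36, FABP1, EHHADH and KLB, had a median of 0.16 over 27 other members, of which 15 were also in lists fixed earlier (limma adjusted p = 0.0325, and adjusted p = 0.17 with an estimated correlation). The 12 members in no earlier list had a median of 0.50 (adjusted p = 0.0132, and adjusted p = 0.151 with an estimated correlation). CIDEC read 0.92 and CREB3L3 0.97, but CPT1A -0.39, ANGPTL4 -0.46 and PLIN2 -0.69 went the other way, so higher PPARA activity may at most account for part of the genes. A general rise of muscle contractile genes, prompted by TNNC1, TNNC2, ACTA1 and SMPX, is argued against by the 27 other members, whose median was 0.00 (limma adjusted p = 0.759).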
